A study of Homo sapiens with 525 samples.

How the data were processed

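Gene expression was measured in 525 samples, 1 Affymetrix array each, from the 60 cell lines of the NCI-60 panel after 2, 6 or 24 h at 0, 10 or 100 nM bortezomib. The deposited values are log2 expression levels per probe set, per the labels; a probe set is a group of short probes on the array that read the same transcript. The normalization method is not given in the sources used here, and the values were used as deposited. Per the labels' protocols, cells were plated a day before the drug was added. The tissue of origin, dose and time of each sample were taken per the labels, and each column of the value table was matched to a sample. No array was a copy of another one (0 array pairs with identical values).

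Of 22277 probe sets 62 control probe sets were left out of the gene tests, and so were 2108 with no gene symbol and 1043 with several. The remaining 19064 carried 1 symbol in the platform's annotation, and 19052 of them had a gene identifier found in the gene table. This gave 11963 genes, of which 4310 had several probe sets and were represented by the probe set with the highest mean over all arrays. Of the genes, 8369 had a probe set not marked as matching several transcripts. Levels near the lower end of the scale (the lowest value was 2.58, the median of the array medians 4.87) cannot be told from background, so falls of dim genes are limited in size, and rises from such levels, as that of HSPA6, are lower bounds.

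For each line, a treated array was compared with the untreated array of the same line and time, and the within-line differences were fitted with limma 3.58.1 in R 4.3.3 (an intercept for each contrast, empirical Bayes moderation), with Benjamini-Hochberg adjustment over all genes. A gene counted as changed at an adjusted p under 0.05 and a mean change of at least 2-fold; counts on adjusted p alone are given too. The pairing comes from the design, as the arrays of a pair are of the same cell line. It was checked on the 2000 most variable genes: each of the 58, 57, 58, 56, 59 and 55 pairs of the 6 contrasts with untreated cells had deviations from the group means correlated at r over 0.1, the lowest at 0.692. With no replicate block, a paired count such as the 2 genes between 100 and 10 nM at 24 h became 0. Doses were compared within line with no untreated array. A change over time was tested as the difference of a line's changes at 2 times. Tissues were compared with the moderated F test on within-line changes, at 100 nM and 6 h and at 10 nM and 24 h. 100 nM and 24 h was not used for tissues, since most leukemia lines have no array there. Leukemia was set against the other tissues as the single tissue contrast fixed in advance.

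Gene lists were tested with camera of limma, at its preset correlation between genes of 0.01 and, beside it, with a correlation estimated from the data, adjusted over the 29 lists. A list member is said to rise or fall at an adjusted p under 0.05 over all genes, whatever its size, and the count adjusted over the list alone is given where it differs. Tissue differences of list means were tested with 100000 permutations of the tissue labels. The contrasts, lists, thresholds and alternatives were set before the data were examined. Genes are named by a rule of the same date: for each contrast with untreated cells the 10 largest mean rises and the 10 largest mean falls among changed genes with that direction in at least 80 percent of the lines, 5 and 5 between doses, for tissue tests the 10 smallest adjusted p, and for a list 2 to 4 members with the largest change, of which those given elsewhere are not always repeated. For the comparisons over time the rule with 10 was applied too, which was settled later.

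The fits were tested on simulated data with the panel's own layout. At 100 nM and 6 h, 49 of 50 genes shifted by 0.25 on the log2 scale were called, and 50 of 50 at 0.5, with 12 of 11763 unshifted genes called. The F test called 91 of 100 genes shifted by 1 in leukemia, the leukemia contrast 98 of 100, and camera 4 of 4 shifted lists and 0 of 25 others. Simulated genes were drawn independently of each other, so this does not cover false list calls that come from correlated genes. Each library was also correlated with the other libraries of its own line over all 11963 genes. The 9 libraries whose highest r lay under 0.985 (0.97 for treated libraries at 24 h) stood apart. These, with the RPMI-8226 library labelled 0 nM at 6 h for its high heat shock genes, make up the libraries in doubt. They were left out as an alternative added later, as were single lines of small tissues and 9 lines of high 3' to 5' signal, those with a median GAPDH 3' minus 5' control signal over 0.4 on the log2 scale (the next line was at 0.209). The alternatives set in advance were unpaired groups, all arrays in 1 fit, an intensity trend with a robust prior, the mean of all probe sets, shared-target probe sets left out, the dimmer genes left out, arrays centred on their median, quantile normalization, only the 48 lines with all 9 arrays, lines of 1 parent averaged, leukemia lines left out, a 1.5-fold threshold, and a rule on the median of the lines. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for tables and figures. Genome positions were not used, and no array was left out of the main results.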

Results

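Bortezomib, a boronic acid drug that blocks the chymotrypsin-like activity of the proteasome and is used against multiple myeloma, was given to the NCI-60 panel, a collection of established human tumour cell lines that serves to screen anticancer drugs. The deposited set held 525 Affymetrix arrays from 60 lines: 6 of breast, 6 of the central nervous system (CNS), 7 of colon, 6 of leukemia (with the myeloma line RPMI-8226), 9 of lung, 9 of melanoma, 7 of ovarian, 2 of prostate and 8 of renal origin. Each line was kept for 2, 6 or 24 h at 0, 10 or 100 nM, with at most 1 array per line, dose and time. The 0 nM groups held 58, 58 and 60 arrays at 2, 6 and 24 h, the 10 nM groups 59, 59 and 59, and the 100 nM groups 59, 58 and 55; 48 lines had all 9 arrays. Array medians ran from 4.68 to 5.02 on the log2 scale, and single values from 2.58 to 14.4. Treated arrays were compared with the untreated array of the same line and time, so each p-value covers the spread between lines, and the number of arrays limits the precision. For each of the 525 arrays the closest other array came from the same line. Of these libraries 10 were held in doubt, 9 as they stood apart from the rest of their line and 1 of RPMI-8226, labelled as untreated, for its high heat shock genes.

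At 2 h and 100 nM, 5 genes passed both thresholds, adjusted p under 0.05 and a mean change of at least 2-fold. DNAJB1, which encodes a cochaperone of the HSP70 proteins, rose by 1.19 ± 0.72 on the log2 scale (SD, n = 57 lines, adjusted p = 7.88e-17, up in 56 lines). BRF2, a subunit gene of an initiation factor of RNA polymerase III, rose by 1.16 ± 0.35 (adjusted p = 1.52e-31, up in 57 lines). HMOX1, which encodes a heme-degrading enzyme, rose by 1.00 ± 0.75 (adjusted p = 4.34e-13, up in 54). HES1, a transcriptional repressor gene downstream of Notch, fell by 1.31 ± 0.78 (adjusted p = 7.79e-17, down in 53 lines). The fifth gene, HSPA6, encodes a strictly stress-inducible HSP70 protein. It rose by 1.24 ± 1.76 (adjusted p = 1.32e-05), in 45 of 57 lines, a share below that asked of named genes, and was chosen after its values were seen. Its untreated mean of 3.90 lay near background, so this rise too is a lower bound. On adjusted p alone, 860 genes rose and 1251 fell, a split that turned to 2697 and 804 when arrays were centred on their median. Fitted with all arrays at once, the cell line as a replicate block, 213 rose and 287 fell. HES1 was read by 2 bright probe sets that both fell here (-1.31 and -1.12). A dim one of mean level 3.36 stayed near 0.

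The gene lists, written before the data were examined, were tested with camera. It asks whether the members of a list as a group rise or fall more than other genes, allowing for correlation between members. Of 29 proteasome subunit genes 26 rose at 100 nM and 2 h (29 adjusted over the list alone), with a median change of 0.08 (camera adjusted p = 3.56e-22). The list of ATF4 and CHOP targets, genes of the amino acid and integrated stress response, had 19 of 23 rise (20 adjusted over the list alone; median 0.19, camera adjusted p = 8.52e-20), among them CHAC1 (0.96 ± 1.04) and DDIT4 (0.79 ± 1.27). Of 26 heat shock and cochaperone genes 17 rose (18 adjusted over the list alone; camera adjusted p = 1.36e-15), with BAG3 at 0.60 ± 0.51. Of 17 NRF2 targets, genes of the oxidative stress response, 13 rose (camera adjusted p = 4.85e-15), with OSGIN1 at 0.74 ± 0.68. Of 20 ER chaperone and ER-associated degradation genes 10 rose and 0 fell (13 and 1 adjusted over the list alone; camera adjusted p = 3.71e-10), HERPUD1 by 0.75 ± 0.47. Of 14 genes for ubiquitin, p97 and their cofactors 8 rose (camera adjusted p = 1.05e-05), ZFAND5 by 0.36 ± 0.34. Of 26 G2 and mitosis genes 18 fell (22 adjusted over the list alone; median -0.12, camera adjusted p = 4.01e-17). Of 27 immediate early genes 15 fell, KLF6 by 0.43 ± 0.47, and 1 rose (16 and 2 adjusted over the list alone, camera adjusted p = 3.86e-07, adjusted p = 0.0558 with an estimated correlation). With probe sets marked as matching several transcripts left out, KLF6 was read by another of its probe sets, at 0.00. Of 20 NF-kB targets 7 fell and 0 rose (7 and 1 adjusted over the list alone; camera adjusted p = 0.0013, and 0.103 with the dimmer genes left out). Of 13 histone genes 4 fell (camera adjusted p = 0.0483, adjusted p = 0.18 with an estimated correlation, and 0.051 to 0.253 in the 8 alternatives that lost the call), and of 19 ribosome biogenesis genes 4 rose (camera adjusted p = 0.0227, adjusted p = 0.134 with an estimated correlation, and 0.602 with no replicate block).

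At 10 nM and 2 h, 0 of 11963 genes passed both thresholds with limma in 58 lines. An unadjusted p under 0.05 was reached by 1583 genes. On adjusted p alone 43 rose, among them ATF3, a stress-induced transcription factor gene (0.24 ± 0.45, adjusted p = 0.00926, up in 43 lines), DNAJB1 (0.20 ± 0.33, adjusted p = 0.00238, up in 49) and ZFAND5 (0.18 ± 0.26, adjusted p = 0.00061, up in 51). Another 165 fell, among them BAX, a pro-apoptotic gene (-0.20 ± 0.42, adjusted p = 0.0351, down in 39). BAX kept an adjusted p under 0.05 in 5 alternatives and lost it in 7 (0.0543 to 1). After centring the 43 and 165 became 191 rising and 109 falling genes. Fitted with all arrays at once, the cell line as a replicate block, these 4 genes had adjusted p from 0.178 to 1, and 3 genes rose and 2 fell. ATF3 also lost it without leukemia lines (adjusted p = 0.0564), and ZFAND5 with shared-target probe sets left out (adjusted p = 0.109). Of the 29 lists 8 passed at the preset correlation of camera. Whether chance gives as many was not tested at this dose and time. At 100 nM and 6 h, 24 of 100 choices of sign for each line's change, the real one included, gave as many or more. Proteasome subunits had 1 of 29 members rise over all genes and 12 adjusted over the list alone (median 0.05, camera adjusted p = 1.61e-09). NRF2 targets had 3 of 17 rise (camera adjusted p = 0.00154) and heat shock genes 1 of 26 (2 adjusted over the list alone; 0.000739). ER chaperones had 1 of 20 rise (2 adjusted over the list alone; 0.00201) and the ubiquitin and p97 list 1 of 14 (0.00645). Immediate early genes had 8 of 27 fall (12 adjusted over the list alone; camera adjusted p = 1.57e-09), G2 and mitosis genes 4 of 26 (12; 1.25e-08) and NF-kB targets 1 of 20 (3; 0.00201). In the fit of all arrays at once 4 of these lists did not pass: ER chaperones (camera adjusted p = 0.076), NRF2 targets (0.076), NF-kB targets (0.125) and G2 and mitosis genes (0.0521). With no replicate block ER chaperones (0.317), NRF2 targets (0.317), NF-kB targets (0.201) and the ubiquitin and p97 list (0.147) did not pass. With shared-target probe sets left out, heat shock genes (0.119), ER chaperones (0.45) and the ubiquitin and p97 list (0.478) did not. Without the libraries in doubt, among them the 10 nM 2 h arrays of MDA-MB-231, NCI-H226 and UO-31, 97 genes rose and 256 fell on adjusted p alone. Without the 9 lines of high 3' to 5' signal, a measure of RNA degradation, those 3 among them, 117 rose and 350 fell. In 28 of 58 lines the changes correlated at r under 0.3 with the mean of the other lines.

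At 6 h HSPA6 rose most, by 4.12 ± 2.67 at 10 nM (n = 58 lines, adjusted p = 1.42e-16, up in 57) and by 5.77 ± 3.11 at 100 nM (n = 56, adjusted p = 2.33e-19, up in 54). Untreated HSPA6 averaged 4.12 in the lines of either dose, near background, so these rises are lower bounds. At 100 nM it was followed by ATF3 (3.45 ± 1.34, adjusted p = 2.58e-25), CHAC1, which encodes a glutathione-degrading enzyme (3.33 ± 1.07), DDIT4, an mTORC1 inhibitor gene (2.98 ± 1.64), DNAJB1 (2.96 ± 0.79), and HMOX1 (2.91 ± 1.44). Then came BAG3 (2.79 ± 0.87), the cystine transporter gene SLC7A11 (2.57 ± 1.30), DNAJB4 (2.36 ± 1.02) and CTH, of cysteine synthesis (2.32 ± 0.95). At 10 nM the next were CHAC1 (2.48 ± 1.30), DDIT4 (2.45 ± 1.46), DNAJB1 (2.40 ± 0.74), ATF3 (2.25 ± 1.27), BAG3 (2.17 ± 0.84), HMOX1 (2.12 ± 1.18), SLC7A11 (1.94 ± 1.38), DNAJB4 (1.84 ± 1.07) and BRF2 (1.78 ± 0.53). In all, 37 genes rose and 5 fell at 10 nM, and 78 rose and 37 fell at 100 nM. Adjusted p alone gave 2216 and 2833, and 2618 and 3408. After centring more genes rose than fell, 3511 and 2094, and 4864 and 2417. The 5 that fell at 10 nM were PSRC1, of the mitotic spindle (-1.29 ± 0.56, adjusted p = 1.51e-23, down in 58), PDP1, a pyruvate dehydrogenase phosphatase gene (-1.09 ± 0.70), FJX1 (-1.01 ± 0.69), HES1 (-1.01 ± 0.68) and, with the smallest of these falls, the Wnt receptor gene FZD2. At 100 nM PSRC1 (-1.84 ± 0.85), PDP1 (-1.42 ± 0.78), FJX1 (-1.39 ± 0.95), FZD2 (-1.38 ± 0.98), and HES1 (-1.38 ± 0.93) fell most. HMGA2, of chromatin architecture (-1.35 ± 0.94), LYSET (-1.32 ± 0.48), TNS3, of focal adhesions (-1.30 ± 0.60), IMP3, of ribosomal RNA processing (-1.30 ± 0.47) and the phosphatase gene DUSP7 (-1.26 ± 0.56) came next. The 78 to 37 split at 100 nM became 89 to 25 when arrays were centred on their median, and 79 to 42 without the libraries in doubt.

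**Figure D1:**
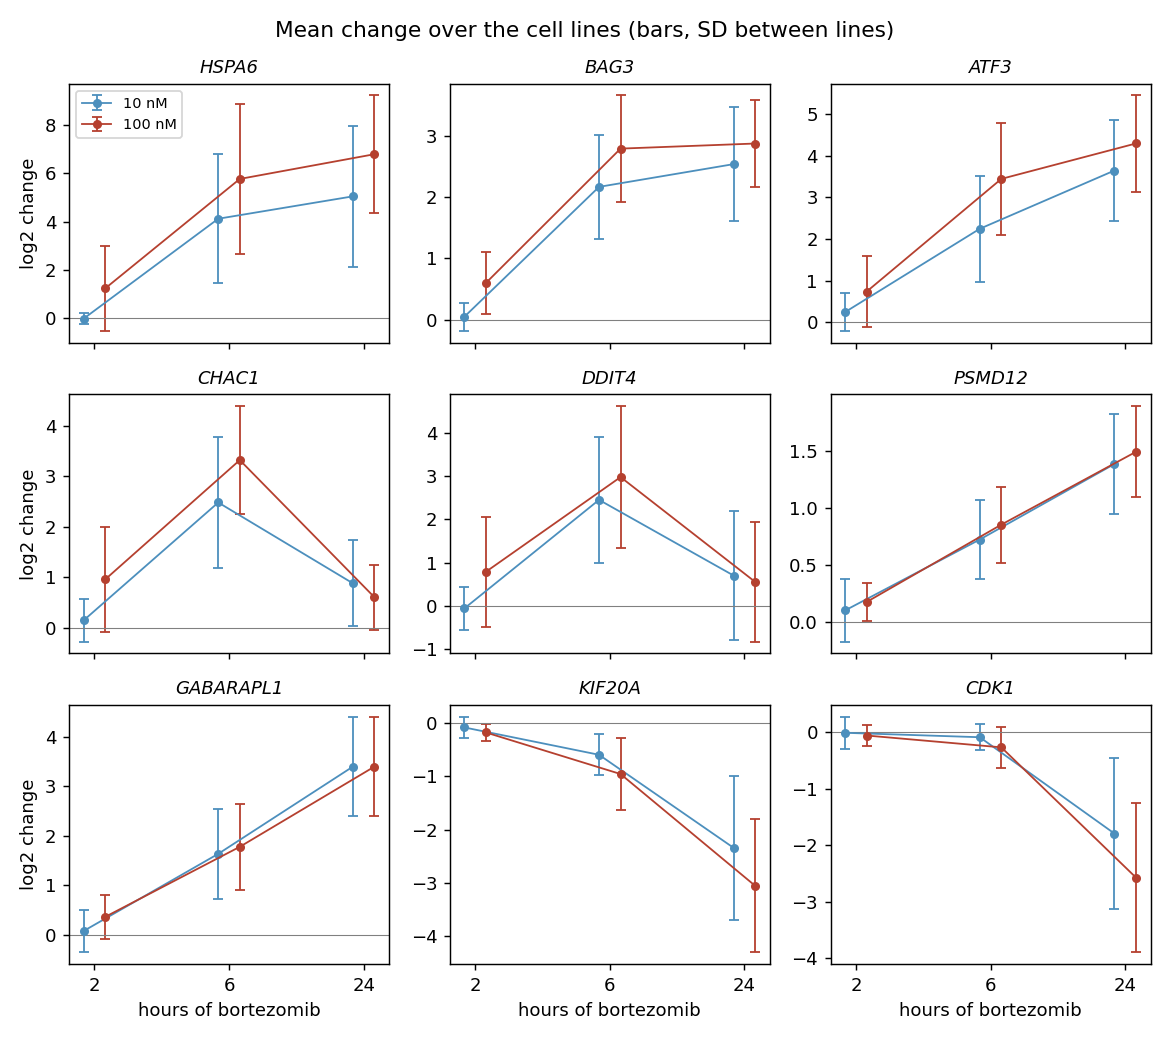
Mean change (± SD over lines) of 9 genes by dose and time. HSPA6 reached 6.80 at 100 nM and 24 h, while CHAC1 went from 3.33 at 6 h to 0.60 at 24 h.

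The 29 proteasome subunit genes all rose at 6 h at both doses, with medians of 0.32 at 10 nM and 0.31 at 100 nM (camera adjusted p = 3.85e-34 and 2.65e-23). PSMD12 rose by 0.86 ± 0.33 and PSMC4 by 0.72 ± 0.28 at 100 nM. Heat shock genes rose in 25 of 26 at both doses (medians 0.38 and 0.67, camera adjusted p = 2.41e-25 and 2.66e-23), HSPH1 by 1.96 ± 0.63 at 100 nM. ATF4 targets rose in 23 of 23 at both doses (medians 0.75 and 1.11, camera adjusted p = 1.03e-21 and 6.09e-24), with PPP1R15A at 1.97 ± 0.71, DDIT3 at 2.20 ± 0.94 and TRIB3 at 2.06 ± 0.89. NRF2 targets rose in 14 and 15 of 17 (camera adjusted p = 9.27e-13 and 1.09e-10), with GCLM at 1.41 ± 0.60 and OSGIN1 at 1.84 ± 0.82. The ubiquitin and p97 list had 12 rise and 1 fall of 14 at 10 nM, and 11 rise and 2 fall at 100 nM (camera adjusted p = 7.24e-10 and 1.43e-06). NPLOC4 rose by 0.63 ± 0.29 and STUB1 fell by 0.36 ± 0.20. ER chaperones had 13 of 20 rise at 10 nM (camera adjusted p = 3.1e-09). At 100 nM 16 rose and 2 fell (camera adjusted p = 1.15e-06, adjusted p = 0.0846 with an estimated correlation). HERPUD1 was at 2.20 ± 0.78 and XBP1 at 1.30 ± 0.57. Of 17 autophagy receptor and ATG8 family genes 8 rose and 4 fell at 10 nM, and 8 rose and 6 fell at 100 nM (camera adjusted p = 0.0027 and 0.0283, adjusted p = 0.138 and 0.275 with an estimated correlation). GABARAPL1 rose by 1.77 ± 0.87 and SQSTM1 by 1.09 ± 0.51, while the list median at 100 nM was 0.02. The call at 100 nM was lost after centring (camera adjusted p = 0.0881), with the dimmer genes left out (0.184) and with shared-target probe sets left out (0.266). The call at 10 nM was lost in the last of these (0.2) and with the dimmer genes left out (0.0567). Of 20 NF-kB targets 5 rose and 1 fell at 10 nM (camera adjusted p = 0.0471, adjusted p = 0.404 with an estimated correlation), CXCL8 by 1.48 ± 1.06. They lost the call in 9 alternatives, with camera adjusted p = 0.0592 without the libraries in doubt and 0.134 after centring. At 100 nM 8 rose and 3 fell (camera adjusted p = 0.14).

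All 26 G2 and mitosis genes fell at 6 h, with medians of -0.33 at 10 nM and -0.52 at 100 nM (camera adjusted p = 4.13e-19 and 1.37e-15; with an estimated correlation, adjusted p = 0.0212 and 0.107). PLK1 fell by 1.09 ± 0.65 at 100 nM and KIF20A by 0.95 ± 0.67. Of 8 metallothionein genes 6 fell at 10 nM and 7 at 100 nM (camera adjusted p = 0.00184 and 6.26e-05, adjusted p = 0.182 and 0.107 with an estimated correlation), with MT1X at -0.74 ± 0.41 and MT1E at -0.67 ± 0.53 at 100 nM. With no replicate block this list did not pass at 10 or 100 nM (camera adjusted p = 0.402 and 0.0684), nor at 10 nM with all arrays in 1 fit (0.0694). Metallothionein genes share sequence, and with probe sets marked as matching several transcripts left out the median at 100 nM was 0.00. Of 29 G1/S and DNA replication genes 17 fell and 4 rose at 10 nM (camera adjusted p = 0.00553, adjusted p = 0.445 with an estimated correlation, and 0.136 with all arrays in 1 fit), and 15 fell and 9 rose at 100 nM (camera adjusted p = 0.314). Of 13 histone genes 7 fell and 1 rose at 100 nM (camera adjusted p = 0.0214, adjusted p = 0.522 with an estimated correlation, and 0.339 with shared-target probe sets left out), H2BC5 by -0.83 ± 0.59. At 100 nM 10 of the 29 lists passed. Of 100 choices of sign for each line's change, the real one among them, 24 gave as many or more, up to 14, so the number of lists does not exclude chance, and the members named here rest on their own tests.

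**Figure D2:**
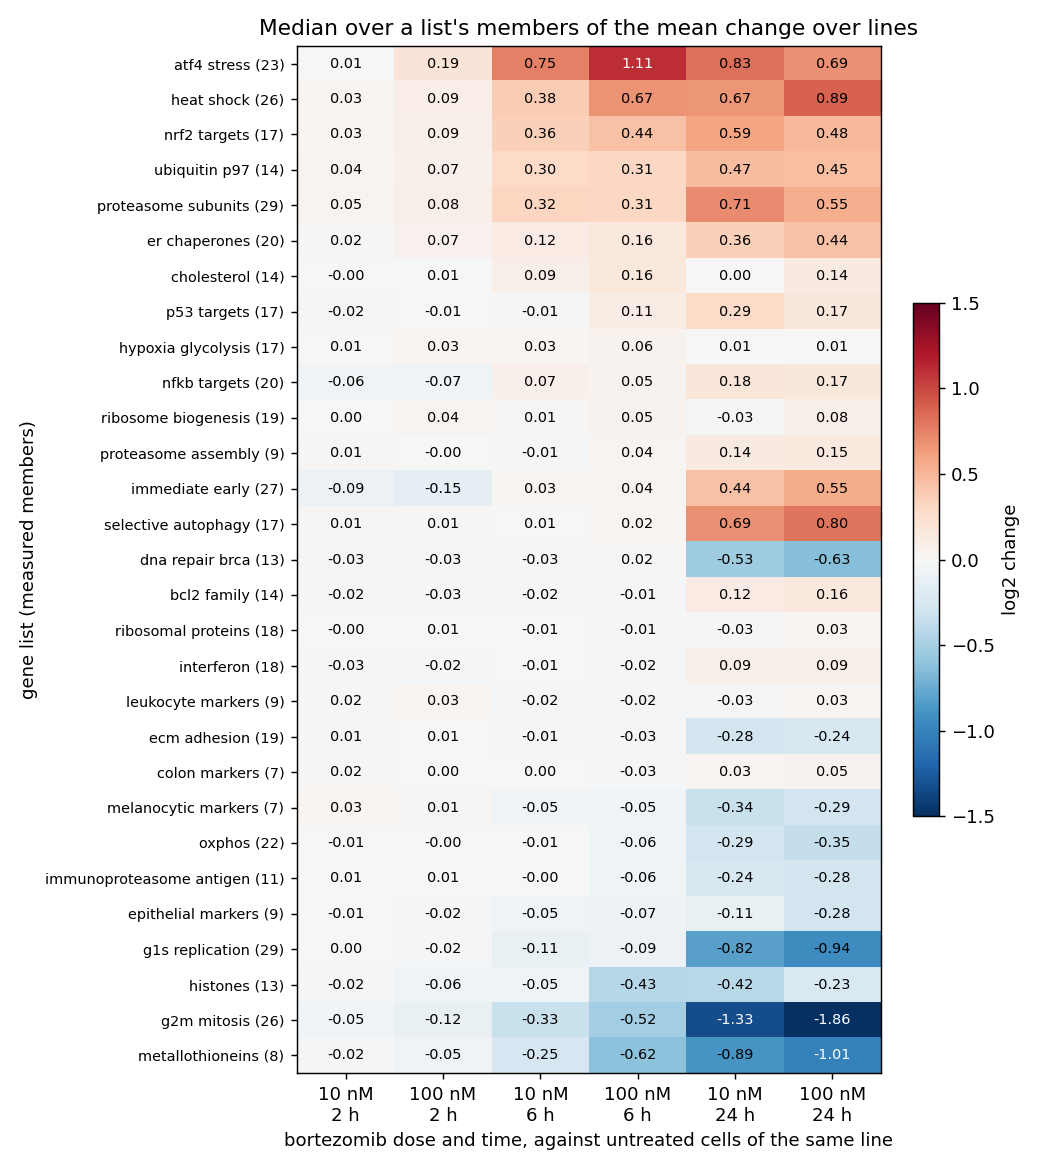
Median change of the members of each gene list at each dose and time. The ATF4 list reached 1.11 at 100 nM and 6 h, and the G2 and mitosis list -1.86 at 100 nM and 24 h.

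At 24 h the largest rises were those of HSPA6, by 5.05 ± 2.93 at 10 nM (n = 59 lines, adjusted p = 5.98e-19, up in 56) and 6.80 ± 2.44 at 100 nM (n = 55, adjusted p = 6.87e-27, up in 54). Both are lower bounds, as untreated HSPA6 averaged 3.94 and 3.95 in these lines, near background. Of the 55 lines at 100 nM, K-562 was the only leukemia line. ATF3 rose by 3.65 ± 1.21 and 4.30 ± 1.16. GABARAPL1, an ATG8 family gene of autophagy, rose by 3.40 ± 1.00 and 3.40 ± 1.00, and CXCL8, a neutrophil chemokine gene, by 2.90 ± 2.03 and 3.37 ± 1.95. PPP1R15A, a phosphatase subunit gene that ends the block on translation, rose by 2.75 ± 0.92 and 3.29 ± 0.74. DDIT3 (2.69 ± 0.83 and 2.94 ± 0.66), DUSP1 (2.68 ± 1.36 and 2.98 ± 1.35), MAFF (2.62 ± 1.53 and 3.04 ± 1.48) and the secreted chaperone gene CLU (2.90 ± 1.68 and 2.90 ± 1.55) rose at both doses. BAG3 completed the 10 nM set (2.54 ± 0.93) and the small heat shock gene CRYAB the 100 nM set (2.90 ± 2.04). The largest falls at 100 nM were those of the mitotic kinesin gene KIF20A (-3.06 ± 1.26, adjusted p = 3.29e-24, down in 55 lines), CCDC85B (-3.04 ± 0.71), TNS3 (-2.71 ± 0.85) and PLK1 (-2.63 ± 1.02). They were followed by TMX4 (-2.60 ± 0.96), CDK1 (-2.57 ± 1.32), TOP2A (-2.53 ± 1.20), the nuclear lamina gene LMNB1 (-2.47 ± 0.94), PSRC1 (-2.42 ± 0.67) and CDCA3 (-2.41 ± 1.02). At 10 nM CCDC85B (-2.76 ± 0.88), TNS3 (-2.42 ± 1.00), KIF20A (-2.35 ± 1.36), TMX4 (-2.19 ± 0.91), PSRC1 (-2.09 ± 0.87), DPM3 (-2.05 ± 0.63), LMNB1 (-2.01 ± 0.96), NREP (-2.01 ± 1.33), PLK1 (-1.92 ± 1.10) and SDHAF3 (-1.90 ± 0.77) fell most. In all, 263 genes rose and 369 fell at 10 nM, and 341 rose and 645 fell at 100 nM. Adjusted p alone gave 4025 and 3884, and 4334 and 3967, and after centring 6998 and 2711, and 7143 and 2736.

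Centring arrays on their median shifted the median change of all genes at 24 h from 0.01 to 0.15 at 10 nM and from 0.02 to 0.20 at 100 nM, and the splits became 380 rising and 224 falling genes, and 553 and 378. Changes of list medians at 24 h are therefore read against shifts of that size. With it and with quantile normalization, each named gene and each list median that passed kept its sign. Centring ended 3 list calls at 24 h, those of immediate early genes (camera adjusted p = 0.0559 at 10 nM and 0.102 at 100 nM) and of NRF2 targets at 10 nM (0.0858). CCDC85B rested on 1 of its probe sets, as another one of mean level 4.17 changed by 0.31 at 100 nM. For TMX4 a second probe set changed by -1.29 at 100 nM and a dim one by 0.06. In 17 of 367 changed genes with several probe sets at 100 nM, a probe set moved the other way. The 3' minus 5' signal of the ACTB control probes, a measure of RNA degradation, rose with treatment at 24 h. It rose by 0.20 ± 0.51 at 10 nM (n = 59, permutation adjusted p = 0.011) and 0.28 ± 0.78 at 100 nM (n = 55, permutation adjusted p = 0.0048). That of GAPDH changed by 0.05 ± 0.23 and 0.09 ± 0.35 (permutation adjusted p = 0.318 and 0.144).

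Proteasome subunit genes rose at 24 h in 29 of 29 at 10 nM (median 0.71, camera adjusted p = 1.83e-21, adjusted p = 0.0542 with an estimated correlation) and in 27 of 29 at 100 nM (median 0.55, camera adjusted p = 1.36e-14, adjusted p = 0.115 with an estimated correlation). PSMD12 rose by 1.39 ± 0.44 at 10 nM and PSMC4 by 1.45 ± 0.36 at 100 nM. Heat shock genes rose in 24 of 26 at 10 nM, and at 100 nM 24 rose and 1 fell (medians 0.67 and 0.89, camera adjusted p = 5.19e-11 and 7.22e-12, adjusted p = 0.158 and 0.115 with an estimated correlation). HSPB8 was at 2.35 ± 1.35 and 2.15 ± 1.25. Of 17 autophagy genes 13 rose and 1 fell at 10 nM, and 12 rose and 1 fell at 100 nM (camera adjusted p = 1.94e-06 and 0.000113, adjusted p = 0.107 and 0.145 with an estimated correlation; 0.07 at 100 nM with shared-target probe sets left out). MAP1LC3B was at 1.87 ± 0.67 and 2.13 ± 0.65 and the receptor gene SQSTM1 at 1.67 ± 0.62 and 1.24 ± 0.72. ER chaperones rose in 15 and 16 of 20 (camera adjusted p = 5.69e-06 and 2.21e-06, adjusted p = 0.254 and 0.178 with an estimated correlation), DNAJB9 by 2.04 ± 0.83 and 2.58 ± 0.73 and HSPA5 by 1.08 ± 0.45 and 1.22 ± 0.37. ATF4 targets had 18 rise and 1 fall of 23 at 10 nM, and 18 rise and 2 fall at 100 nM (camera adjusted p = 6.54e-07 and 3.01e-06, adjusted p = 0.182 and 0.115 with an estimated correlation). The ubiquitin and p97 list had 11 rise and 3 fall of 14 at both doses (camera adjusted p = 0.000116 and 0.00323, adjusted p = 0.143 and 0.178 with an estimated correlation), UFD1 by 1.25 ± 0.35 and 1.15 ± 0.29. Of 27 immediate early genes 17 rose and 3 fell at 10 nM, and 16 rose and 3 fell at 100 nM (camera adjusted p = 0.00142 and 0.00323, adjusted p = 0.254 and 0.178 with an estimated correlation). JUN was at 1.96 ± 1.24 and 2.08 ± 1.31. NRF2 targets had 10 rise and 3 fall of 17 at 10 nM (camera adjusted p = 0.00974, adjusted p = 0.435 with an estimated correlation), and 10 rise and 4 fall at 100 nM (camera adjusted p = 0.0683). HMOX1 was at 2.17 ± 1.38 and NQO1 at -0.85 ± 0.71 at 100 nM.

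Of the 26 G2 and mitosis genes 26 fell at 24 h at both doses, 25 of them at least 2-fold at 100 nM (medians -1.33 and -1.86, camera adjusted p = 3.7e-12 and 3.42e-15, adjusted p = 0.254 and 0.165 with an estimated correlation). G1/S and replication genes fell in 24 of 29 at both doses, with 0 and 2 rising (camera adjusted p = 5.73e-07 and 2.21e-06, adjusted p = 0.415 and 0.471 with an estimated correlation). POLE2 fell by 1.43 ± 0.91 at 10 nM and CCND1 changed by -1.32 ± 0.97. Respiratory chain genes fell in 19 and 20 of 22 (medians -0.29 and -0.35, camera adjusted p = 2.98e-05 and 1.8e-06, adjusted p = 0.254 and 0.165 with an estimated correlation). CYC1 was at -0.95 ± 0.32 at 100 nM. After centring, 13 fell and 3 rose at 100 nM. Of 13 homologous recombination and Fanconi genes 11 and 12 fell (camera adjusted p = 0.0032 and 0.00323, adjusted p = 0.491 and 0.471 with an estimated correlation, and 0.0594 and 0.0816 with the dimmer genes left out), with BARD1 at -0.81 ± 0.88 and -1.07 ± 0.87. Of 8 metallothionein genes 7 fell and 1 rose at both doses (camera adjusted p = 0.00526 and 0.0108, adjusted p = 0.365 and 0.471 with an estimated correlation). With probe sets marked as matching several transcripts left out the medians were 0.08 and 0.13, the other way. With no replicate block the metallothionein list did not pass (camera adjusted p = 0.106 and 0.153). The ACTB shift in 3' minus 5' signal ran alongside these falls.

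Several lists split at 24 h without passing. Among immunoproteasome and antigen presentation genes 7 of 11 fell and 3 rose at both doses (camera adjusted p = 0.2 and 0.178). The inducible catalytic subunit genes PSMB9 (-1.43 ± 0.95 and -1.60 ± 0.98), PSMB10 (-1.36 ± 0.63 and -1.47 ± 0.64) and PSMB8 (-0.96 ± 0.60 and -1.02 ± 0.67) fell. HLA-E rose (0.67 ± 0.48 and 0.82 ± 0.47). Of 17 p53 targets 8 rose and 6 fell at 100 nM (camera adjusted p = 0.494), with GADD45A at 2.56 ± 1.04, CDKN1A at 1.58 ± 1.06, TP53I3 at -1.40 ± 0.65 and DDB2 at -1.39 ± 0.70. Of 14 BCL2 family genes 7 rose and 4 fell (camera adjusted p = 0.494), PMAIP1 by 1.99 ± 0.92 and BCL2L1 by -1.01 ± 0.58. Of 17 hypoxia and glycolysis genes 7 rose and 7 fell (camera adjusted p = 0.708), with NDRG1 at 1.89 ± 1.10 and SLC2A1 at -1.16 ± 0.90. Of 14 cholesterol genes 7 rose and 6 fell (camera adjusted p = 0.727), with HMGCS1 at 1.27 ± 0.85 and EBP at -1.01 ± 0.55. NF-kB targets had 8 of 20 rise and 6 fall (camera adjusted p = 0.506), CXCL2 by 1.49 ± 1.54 and CXCL3 by 1.47 ± 1.36. Interferon-stimulated genes had 5 of 18 rise and 4 fall (camera adjusted p = 0.636), with MX1 at 1.00 ± 0.98. Proteasome assembly genes had 5 of 9 rise and 4 fall (camera adjusted p = 0.662), with PSME4 at 0.92 ± 0.40 and PSMD10 at -0.83 ± 0.61. Extracellular matrix genes had 3 of 19 rise and 10 fall (camera adjusted p = 0.406), with THBS1 at -1.06 ± 1.34. With probe sets marked as matching several transcripts left out, THBS1 was read by another of its probe sets, at 0.05. Of 19 ribosome biogenesis genes 7 rose and 4 fell (camera adjusted p = 0.494), RRP12 by 1.11 ± 0.59. Of 13 histone genes 3 rose and 6 fell (camera adjusted p = 0.494), and of 18 ribosomal protein genes 8 rose and 2 fell (camera adjusted p = 0.406). After centring, the counts at 100 nM were 14 and 3 for ribosome biogenesis, 18 and 0 for ribosomal proteins, 9 and 1 for interferon genes, 13 and 4 for NF-kB targets and 10 and 3 for hypoxia genes. Of the tissue marker lists, melanocytic markers had 5 of 7 fall (6 adjusted over the list alone; camera adjusted p = 0.407). Epithelial markers had 6 of 9 fall and 1 rise (camera adjusted p = 0.406), KRT19 by -1.07 ± 1.31. Leukocyte markers had 2 rise and 2 fall of 9 (camera adjusted p = 0.817, with a median of 0.03, a mean of -0.07 and a test direction of up), and intestinal markers 1 rise of 7 (0 adjusted over the list alone; camera adjusted p = 0.858). After centring, 1 melanocytic marker fell and 0 rose, 2 epithelial markers fell and 1 rose, 6 leukocyte markers rose and 1 fell, and 5 intestinal markers rose and 0 fell.

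Genes that passed at 6 h mostly passed at 24 h, which has its own untreated arrays. At 10 nM 35 of the 37 rising genes rose again at least 2-fold, against 0.813 expected (Fisher p = 5.95e-57), and 3 of the 5 falling genes, HES1 not among them, fell again, against 0.154 expected (Fisher p = 0.000278). At 100 nM 59 of 78 rose again, against 2.22 expected (Fisher p = 1.65e-76), and 26 of 37 fell again, against 2.00 expected (Fisher p = 3.18e-25). None went from a rise to a fall or back. Most lines, but not all, were used at both times: 57 had both changes at 10 nM and 51 at 100 nM. At 100 nM no leukemia line had both. HES1 was at 0.34 at 10 nM and 0.76 at 100 nM at 24 h, but its other bright probe set was at -0.38 and -0.40.

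Between 100 and 10 nM, compared with no shared untreated array, HSPA6 differed by 1.24 ± 1.66 at 2 h (n = 58 lines, adjusted p = 1.33e-05, higher in 51; a lower bound, as its 10 nM level was near background), 1.57 ± 1.92 at 6 h (n = 57, adjusted p = 3.17e-07, higher in 53) and 1.69 ± 1.45 at 24 h (n = 55, adjusted p = 1.34e-10, higher in 54). ATF3 was higher at 100 nM by 1.19 ± 1.07 at 6 h (adjusted p = 1.48e-10, in 53 lines), and ID2, an inhibitor gene of helix-loop-helix factors, by 1.01 ± 0.90 at 24 h (adjusted p = 3.34e-10, in 51 lines). These were the 1, 2 and 2 genes past both thresholds at 2, 6 and 24 h. Adjusted p alone gave 293 higher and 366 lower genes at 2 h, 1476 and 2075 at 6 h, and 1620 and 2646 at 24 h. After centring the majority turned at each time, to 422 and 300, 2090 and 1573, and 3754 and 1990. Fitted with all arrays at once, the cell line as a replicate block, the counts were 55 and 41, 796 and 1020, and 1361 and 2162. ATF4 targets were higher at 100 nM in 16 of 23 at 2 h (19 adjusted over the list alone; median 0.20, camera adjusted p = 2.43e-30) and in 23 at 6 h (median 0.49, camera adjusted p = 5.32e-25). Heat shock genes were higher in 23 of 26 at 6 h (24 adjusted over the list alone; camera adjusted p = 7.29e-21). Metallothioneins were lower in 7 of 8 at 6 h (camera adjusted p = 7.35e-07), but with shared-target probe sets left out their median changes from untreated cells were -0.0049 at 10 nM and 0.0022 at 100 nM. At 24 h proteasome subunits were lower at 100 nM in 22 of 29 (23 adjusted over the list alone; median -0.12, camera adjusted p = 3.22e-10, adjusted p = 0.0955 with an estimated correlation). G2 and mitosis genes were lower in 26 of 26 (median -0.45, camera adjusted p = 7.67e-13, adjusted p = 0.217 with an estimated correlation). With no replicate block, that is without pairing by line, HSPA6 had adjusted p = 0.263 at 6 h (2.87e-13 to 1.06e-05 over the other alternatives) and 0.154 at 24 h (1.71e-12 to 4.53e-07), and ID2 had 0.142 (8.44e-12 to 2.08e-08), leaving 1 gene at 6 h and 0 at 24 h.

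Between 2 and 6 h the change at 100 nM grew most for HSPA6 (4.60 ± 3.50, n = 53 lines, adjusted p = 6.26e-13, in 51 lines; its untreated levels were near background), ATF3 (2.77 ± 1.43), CHAC1 (2.41 ± 1.44), DDIT4 (2.20 ± 1.72), BAG3 (2.20 ± 1.05), CXCL8 (2.19 ± 1.48), CTH (2.13 ± 0.95), SLC7A11 (2.06 ± 1.07), TRIB3 (1.87 ± 0.90) and HMOX1 (1.86 ± 1.32). It went down at least 2-fold for 7 genes, PSRC1 (-1.30 ± 0.80), TNS3 (-1.23 ± 0.60), DUSP7 (-1.12 ± 0.64), LYSET (-1.11 ± 0.59), IMP3 (-1.09 ± 0.48), FZD2 (-1.08 ± 0.89) and NREP (-1.07 ± 0.83), and it went up for 51. ATF4 targets grew in 23 of 23 (median 0.99, camera adjusted p = 9.35e-27) and heat shock genes in 25 of 26 (median 0.64, camera adjusted p = 8.17e-25). Proteasome subunits grew in 27 of 29 (28 adjusted over the list alone; camera adjusted p = 5.33e-20).

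From 6 to 24 h the change at 100 nM went down most for CHAC1 (-2.74 ± 0.96, n = 51 lines, adjusted p = 1.08e-24, in 51 lines) and DDIT4 (-2.61 ± 1.25, adjusted p = 1.68e-19, in 51 lines). Both had been among the largest rises at 6 h. Next came CDK1 (-2.20 ± 1.23), TMX4 (-2.13 ± 1.07), KIF20A (-2.08 ± 1.06), CCDC85B (-1.98 ± 0.71, with a second probe set at 0.17), NIPSNAP2 (-1.89 ± 0.56), COQ2 (-1.84 ± 0.59), SUCLG2 (-1.79 ± 0.68) and TOP2A (-1.77 ± 1.11). It went up most for GEM, which encodes a small GTPase (2.45 ± 1.23, adjusted p = 1.14e-18, in 50 lines), CRYAB (2.38 ± 1.62), HES1 (2.15 ± 1.46; its other bright probe set was at -1.26 at 6 h and -0.40 at 24 h), CLU (2.05 ± 1.15), the collagenase gene MMP1 (2.02 ± 1.64) and the deubiquitinase gene CYLD (1.72 ± 0.93). CD55 (1.69 ± 1.02), MAFF (1.64 ± 0.99), C3orf52 (1.59 ± 0.77) and GABARAPL1 (1.57 ± 0.80) came next. No leukemia line was in this comparison, as K-562 has no 100 nM array at 6 h and the other leukemia lines have none at 24 h. In all, 83 genes went up and 235 down. After centring, which moved the median of all genes from 0.02 to 0.14, 140 went up and 148 down, and after quantile normalization 123 and 170. ATF4 targets split into 6 up and 14 down (15 down adjusted over the list alone; median -0.58, camera adjusted p = 0.00347, adjusted p = 0.294 with an estimated correlation). Heat shock genes had 7 up and 6 down of 26 (camera adjusted p = 0.786; 14 and 4 after centring). Proteasome subunits had 20 up and 1 down of 29 (camera adjusted p = 2.3e-06, adjusted p = 0.292 with an estimated correlation). G2 and mitosis genes had 26 down of 26 (median -1.24, camera adjusted p = 6.12e-18, adjusted p = 0.208 with an estimated correlation). The 3' minus 5' signal of ACTB, which shifted at 24 h, changed by -0.02 ± 0.41 at 100 nM and 6 h (n = 56, permutation adjusted p = 0.852).

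In untreated cells MAFF was the single gene past both thresholds between 2 and 24 h, falling by 1.09 ± 0.92 (n = 58 lines, adjusted p = 1.04e-11, down in 51; adjusted p = 0.133 with no replicate block, 1.95e-13 to 4.29e-10 over the other alternatives). On adjusted p alone 2586 genes rose and 1846 fell, and after centring 1776 rose and 2854 fell. Ribosome biogenesis genes fell in 17 of 19 (median -0.16, camera adjusted p = 3.08e-09, adjusted p = 0.136 with an estimated correlation), and G1/S genes in 19 of 29 (22 adjusted over the list alone; camera adjusted p = 1.52e-07, adjusted p = 0.362 with an estimated correlation). Respiratory chain genes rose in 18 of 22 (20 rose and 1 fell adjusted over the list alone; median 0.09, camera adjusted p = 1.66e-07, adjusted p = 0.116 with an estimated correlation).

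By tissue, genes of the melanocytic lineage stood out at 10 nM and 24 h. In the 9 melanoma lines TYR, the key enzyme gene of melanin synthesis, changed by -3.06 ± 1.49 (limma F adjusted p = 1.93e-11), and MITF, the master regulator gene of melanocytes, by -2.68 ± 1.15 (adjusted p = 4.94e-10). SOX10 changed by -2.54 ± 1.37 (adjusted p = 1.93e-10). CPN1 (-2.87 ± 1.28), EDNRB (-1.42 ± 0.37), CAPN3 (-2.64 ± 1.24), S100A1 (-2.51 ± 1.15), GJB1 (-3.15 ± 1.18), MYEF2 (-1.97 ± 1.02) and GAS7 (-2.27 ± 1.03) were also lowest in melanoma. The melanocytic list changed by -2.09 ± 1.07 in melanoma and by -0.11 to 0.12 in the means of the other tissues (permutation F adjusted p = 0.00029). The melanoma line LOX, whose 10 nM 24 h library was among those in doubt, did not fall (0.11), and the other 8 melanoma lines were at -3.54 to -1.58. SCD5, a desaturase gene, rose in leukemia (3.21 ± 1.16, adjusted p = 2.37e-10) against 0.14 to 0.58 elsewhere. In the 7 colon lines VIL1, of the brush border, changed by -2.63 ± 1.77 (adjusted p = 2.81e-08) and MYB by -3.43 ± 1.63 (adjusted p = 5.76e-06). The intestinal list changed by -0.84 ± 0.75 there (permutation F adjusted p = 0.00696). In leukemia the leukocyte list changed by -0.53 ± 0.31 (permutation F adjusted p = 0.00029; -0.40 without RPMI-8226) and in colon by -0.37 ± 0.28, against means of -0.27 to 0.08 in the other tissues. In leukemia IKZF1 was at -0.80 ± 0.23 (adjusted p = 2.53e-05). At 100 nM and 6 h SOX10 (-1.90 ± 1.11, adjusted p = 6.05e-08), ID4 (-1.58, adjusted p = 2.63e-06), TBX2 (-1.52 ± 0.94, adjusted p = 2.63e-06) and MITF (-1.30 ± 0.84, adjusted p = 0.000119) were already lower in melanoma. So were ZC3H13 (-0.70 ± 0.34), TPST1 (-0.94 ± 0.55), ZEB2 (-1.42 ± 0.77) and ALX1 (-1.35 ± 0.72), while PTPRCAP was lowest in leukemia (adjusted p = 2.63e-06). VSNL1 (-1.71 ± 0.95) and SCNN1A (-1.13 ± 0.55) were lower in colon. The melanocytic list changed by -0.75 ± 0.45 in melanoma (permutation F adjusted p = 0.000145), and by 0.05 in LOX, whose 6 h libraries were not among those in doubt. Means of the proteasome list at 10 nM and 24 h ran from 0.40 ± 0.18 in leukemia to 0.87 ± 0.12 in breast (permutation F adjusted p = 0.0165). The tissue difference of heat shock genes had adjusted p = 0.0938 and that of ATF4 targets 0.197. In all, 14 of the 29 lists differed between tissues at 10 nM and 24 h, among them ribosome biogenesis (0.00087), immediate early (0.00449), BCL2 family (0.00808), extracellular matrix (0.00808), respiratory chain (0.0102) and cholesterol genes (0.0128). At 100 nM and 6 h 8 of 29 did, among them the leukocyte list (0.000145) and the immunoproteasome and antigen presentation list (0.00822). The F test passed 559 genes at 100 nM and 6 h (n = 56 lines) and 3130 at 10 nM and 24 h (n = 59). With no replicate block it passed 0 and 43. Lines with 1 parent (MDA-MB-435 and M14, NCI-ADR-RES and OVCAR-8, SNB-19 and U251) were counted as separate lines. For genes that fell in 1 tissue, these tests do not tell a smaller response elsewhere from levels near background there.

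**Figure D3:**
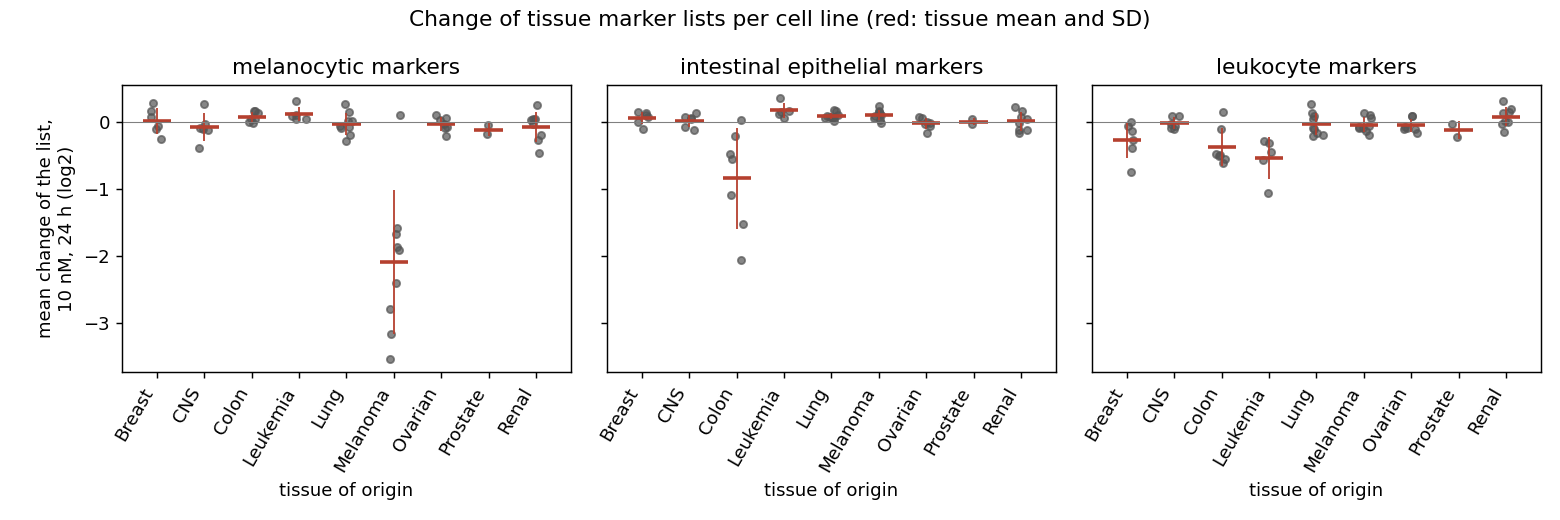
Mean change of the melanocytic, intestinal and leukocyte marker lists in each line at 10 nM and 24 h, by tissue. The melanocytic list averaged -2.09 in melanoma.

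In leukemia against the other tissues at 100 nM and 6 h (5 against 51 lines), the 10 genes of smallest adjusted p were all lower. Falls of dim genes are limited in size, so this does not tell a smaller response in the other tissues from levels near background there. PTPRCAP, which encodes a partner of the CD45 phosphatase, differed by -1.21 (limma adjusted p = 3.44e-10), the adhesion ligand gene SELPLG by -1.44 (adjusted p = 4.25e-08), PIK3CG by -0.80 (adjusted p = 4.25e-08) and the transcription factor gene IKZF1 by -1.07 (adjusted p = 1.52e-07). PTPN7 (-0.98, adjusted p = 3.07e-07), PTPN22 (-0.99, adjusted p = 5.33e-06; 0.20 with shared-target probe sets left out), SASH3 (-1.04, adjusted p = 6.14e-06), AIF1 (-1.14, adjusted p = 1.2e-05), SLA (-0.98, adjusted p = 1.36e-05) and GFI1 (-0.98, adjusted p = 1.49e-05) came next. H2AC17, a histone gene chosen after its values were seen, was higher (1.31, adjusted p = 2.16e-05; 0.78 without HL-60). In all, 36 genes were higher and 23 lower. Of the 5 leukemia lines RPMI-8226 drove part of that count. Its library labelled 0 nM at 6 h held HSPA6 at 12.3 and its library labelled 100 nM held it at 3.99, with the embryonic globin genes HBZ at 11.8 and HBE1 at 12.7. Without RPMI-8226, 9 genes were higher and 27 lower, and PTPRCAP was at -1.49 (adjusted p = 5.03e-16). HSPA6 then went from -4.80 (adjusted p = 0.0165) to -2.38 (adjusted p = 0.317), HMOX1 from -2.30 (adjusted p = 0.011) to -1.37 (adjusted p = 0.2). HBZ, chosen after its values were seen, went from 1.70 (adjusted p = 0.0272) to 0.01 (adjusted p = 0.988). VLDLR, an ATF4 target, was higher by 1.75 (adjusted p = 0.00534), and by 1.21 (adjusted p = 0.109) without MOLT-4. Left out in turn, single leukemia lines gave 36 to 106 genes; with no replicate block 2 genes passed, and PTPRCAP had adjusted p = 1 (3.15e-16 to 2.01e-07 over the other alternatives).

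**Figure D4:**
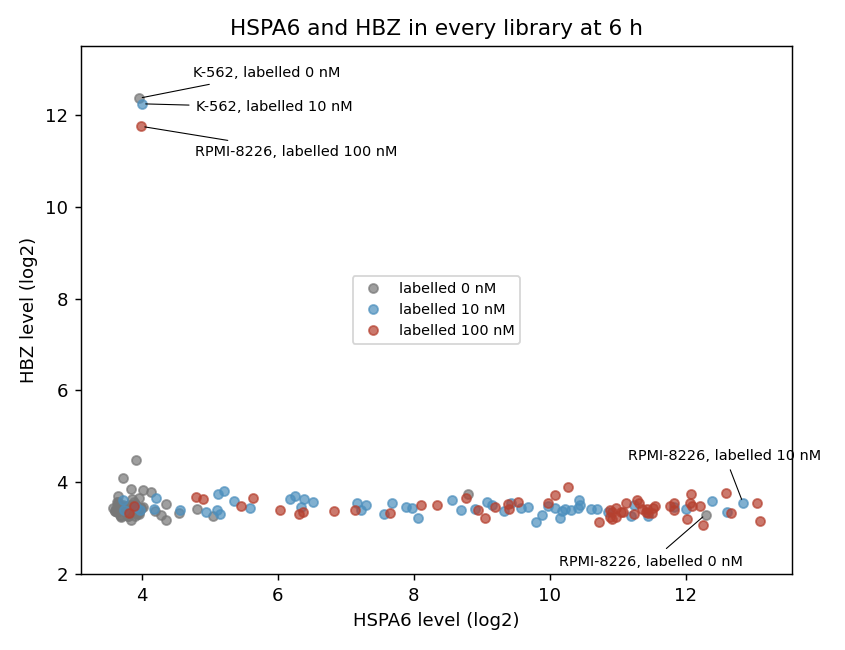
HSPA6 against HBZ level in each 6 h library. The RPMI-8226 library labelled 0 nM lay at an HSPA6 level of 12.3, and the one labelled 100 nM at an HBZ level of 11.8.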

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

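The tests on RPMI-8226 and those of a drug response, of a library property and of the control probes in the 3 libraries at 10 nM and 2 h were chosen after the results were seen; the GAPDH test over untreated libraries and the splits of the samples were written down before.

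The 6 h changes of RPMI-8226 at 100 nM ran against those of the panel (r = -0.46 with the mean of the other lines), with the heat shock list at -0.68 where the other leukemia lines had 0.794 to 1.38. A lasting opposite response of this line was argued against, as its lowest correlation at the other doses and times was 0.406. The library labelled 0 nM at 6 h had a heat shock mean of 9.74, above the 7.97 to 9.26 of the other 57 untreated libraries, so a treated culture labelled as untreated may explain its part. In the library labelled 100 nM, 46 genes that are high in K-562 and low in RPMI-8226 stood at a median share of 0.378 of their K-562 level, against at most 0.0241 for any other library and line, with HBZ at 11.8 and HBE1 at 12.7 and a median rise of 1.66 for the 6 measured of the listed erythroid genes, of which 4 rose by 1 or more, which is consistent with RNA of K-562 in it. How this came about stays open, and K-562 has no 100 nM library at 6 h to compare. HSPA6 stood at 3.988 in this RPMI-8226 library, against 12.84 in the line's library at 10 nM and 6 h and 10.23 at 100 nM and 2 h. K-562 RNA at a share of 0.378 leaves that low HSPA6 level unexplained. The library's heat shock mean of 9.057 lay above the 8.431 and 8.457 of the line's untreated libraries at 2 and 24 h. Whether its RPMI-8226 RNA came from treated cells was not tested.

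The 10 nM 2 h libraries of MDA-MB-231, NCI-H226 and UO-31 shared a change of 953, 1627 and 1908 genes by at least 2-fold (pairwise r from 0.756 to 0.825), against a median of 7.5 genes per line. A drug response was argued against, since the same genes at 100 nM and 2 h followed with slopes of at most 0.107. Untreated libraries carried the pattern too, so a property of single libraries that is independent of the treatment is a candidate explanation. The highest, all at 24 h, were IGR-OV1 (r = 0.804), NCI-H226 (0.755), SN12C (0.658) and MDA-MB-231 (0.646). All are among the 9 lines of high 3' to 5' signal, so this property was not told apart from RNA integrity. The GAPDH 3' minus 5' signal changed by -1.22, -1.23 and -1.74 in the 3 (median -1.23), outside the -0.337 to 1.07 of the other 55 lines. That of ACTB changed by -2.42, -2.78 and -3.92, against -0.921 to 1.67, so RNA integrity is a candidate too. The 3 libraries themselves lay near the median of all libraries (GAPDH -0.0482, 0.0121 and -0.117, against -0.111). The other libraries of the same lines had medians of 1.19, 0.99 and 1.26, so it was these that stood apart from the panel. Over 60 untreated libraries, which are not the 3, the GAPDH signal gave Spearman rho = -0.0503 with the pattern (permutation p = 0.699; Pearson r = 0.282, permutation p = 0.032, and 0.187 without the 2 farthest), which decides nothing on the 3, as it set levels across lines against deviations within a line.

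The counts that differed between groups were 559 genes between tissues at 100 nM and 6 h, 3130 at 10 nM and 24 h, 59 between leukemia and the other tissues, and 58 and 318 for the change at 100 nM from 2 to 6 h and from 6 to 24 h. Of 100 splits of each, the real one was the highest (1 of 100), with at most 85, 32, 11, 0 and 0 in another split. For the changes over time, flipped signs pull means toward 0, so few genes can reach a 2-fold mean in another split. On adjusted p alone these had 5066 (2 to 6 h) and 6497 genes (6 to 24 h), with at most 1 and 1 in another split. The 59 fell to 36 without RPMI-8226, for which no splits were drawn.

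Of 80 groups of lines tested for a line apart from the others of its tissue 8 had one, where chance gives about 1 in 20, or 4, so single cases carry little weight. At 100 nM and 6 h, besides RPMI-8226, the heat shock list changed by 0.518 in NCI-H460 (other lung lines 1.17 to 1.57). It changed by 2.06 in TK-10 (other renal lines 0.947 to 1.21), whose untreated 6 h library was among those in doubt. The proteasome list changed by 0.804 in COLO-205 (other colon lines 0.275 to 0.438). The melanocytic list changed by -0.279 in OVCAR-4 (other ovarian lines -0.0672 to 0.0736). At 10 nM and 24 h the heat shock list changed by 2.25 in T-47D (other breast lines 1.18 to 1.45). The G2 and mitosis list changed by -0.534 in SF-295 (other CNS lines -1.84 to -1.38). The melanocytic list changed by 0.306 in CCRF-CEM (other leukemia lines 0.0474 to 0.109).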

How the results depend on the processing

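Leaving out the libraries in doubt, the 9 lines of high 3' to 5' signal, and single lines of small tissues was chosen after results were seen; the other alternatives were set in advance. For none of the moved values was the cause tested, except where the construction of the alternative shows it.

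A 1.5-fold threshold gave 1 gene at 10 nM and 2 h, 25 at 100 nM and 2 h, 227 and 571 at 6 h (10 and 100 nM) and 2114 and 2651 at 24 h. It gave 9, 19 and 25 genes between 100 and 10 nM at 2, 6 and 24 h, 353 and 1455 for the change from 2 to 6 h and from 6 to 24 h, and 21 in untreated cells. A lower threshold can call no fewer genes.

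With shared-target probe sets left out, which leaves 8369 of the 11963 genes, 3 genes passed at 100 nM and 2 h, 20 and 67 at 6 h and 386 and 598 at 24 h (10 and 100 nM). Between doses 1 gene passed at 6 h and 1 at 24 h, over time 30 (2 to 6 h) and 202 (6 to 24 h), between tissues 364 (100 nM and 6 h) and 2005 (10 nM and 24 h), and in the leukemia contrast 34. By construction this setting also reads some genes by a dimmer probe set, and 10 values took the other sign with it. These were HES1 at 100 nM and 2 h (0.0039), CCDC85B at 10 nM and 24 h (0.21), at 100 nM and 24 h (0.31) and from 6 to 24 h (0.17), THBS1 at 100 nM and 24 h (0.0503), PTPN22 in the leukemia contrast (0.20), the median of the ubiquitin and p97 list at 10 nM and 2 h (-0.0064), and the metallothionein medians at 100 nM and 6 h (0.0022), 10 nM and 24 h (0.078) and 100 nM and 24 h (0.133). With leukemia lines left out the autophagy median at 10 nM and 6 h was -0.0056.

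With no replicate block, that is without pairing, 1 gene passed between doses at 6 h and 0 at 24 h, 0 in untreated cells, 0 and 43 between tissues (100 nM and 6 h, 10 nM and 24 h) and 2 in the leukemia contrast; the other 2-fold counts moved by less than 1.5 times, and 68 of 97 named gene calls lost over the alternatives were lost here. On adjusted p alone it gave 9 rising and 5 falling genes at 100 nM and 2 h against 860 and 1251. The rule on the median of the lines gave 0 genes between doses at 2 h, 1 at 24 h, and 2 in untreated cells. The mean of all probe sets gave 1 between doses at 24 h and 0 in untreated cells. Only lines with all 9 arrays gave 4 between doses at 24 h, 2 in untreated cells, and 336 and 1679 between tissues; no leukemia line has all 9 arrays. With the dimmer genes left out, 337 genes differed between tissues at 100 nM and 6 h.

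Without the libraries in doubt, 2 genes passed in untreated cells and 35 in the leukemia contrast, 18 of them among the 59 of the full set. Without the lines of high 3' to 5' signal 2 genes passed between doses at 2 h and 4 at 24 h. Leaving out RPMI-8226 gave 36 genes in the leukemia contrast and leaving out SR 106. At 10 nM and 2 h 4 lists passed with no replicate block, 4 with all arrays in 1 fit and 5 with shared-target probe sets left out, against 8. Over all results and alternatives 49 counts moved by over 1.5 times and 265 did not; of the list medians that passed 5 took the other sign, 53 lost the call and 787 kept both, and of the named genes 6, 97 and 4997.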

Other observations

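The tests in this part were written down before their results were seen, and the patterns they weigh were noticed in the same data.

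Genes that mark a tissue fell in that tissue at 10 nM and 24 h. The 50 genes that most set a tissue apart in untreated cells at 2 h had median changes of -1.24 in melanoma, -1.06 in breast, -1.03 in CNS, -0.89 in renal, -0.50 in colon, -0.48 in leukemia, -0.46 in lung, -0.35 in ovarian and -0.21 in prostate lines, while the same genes had medians from -0.23 (renal set) to 0.01 (melanoma set) in the other tissues. In 8 of 9 tissues the markers fell more than other genes of like level in the same lines. Their median lay below all 1000 random sets matched on level, prostate with 2 lines being the exception. Margins were smallest in colon (-0.501, lowest set -0.487) and ovarian lines (-0.354, lowest set -0.319). The sets did not keep how markers vary together, so their range may be too narrow. They also do not show whether the same genes fell less in other tissues through levels near background there. Averaging lines of 1 parent left melanoma at -1.17. This joined only M14 and MDA-MB-435 among its 9 lines and could move the median little. It therefore decides little on counting such lines separately. What lowered these genes was not tested.

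The response to 10 nM varied between lines, with the heat shock list at 24 h from -0.00403 in NCI-H460, 0.116 in NCI-ADR-RES and 0.253 in HL-60 to 1.85 in MALME-3M, 1.88 in SNB-75 and 2.25 in T-47D. Lines with a larger change at 6 h had a larger one at 24 h (Spearman rho = 0.373, permutation p = 0.00445, adjusted p = 0.0134, n = 57). Pearson r was 0.453, and 0.406 without the 2 farthest lines. This cannot tell onset from resistance, as lines slow to respond may be low at both times. For the mRNA of ABCB1, a drug efflux pump, rho was -0.0573 at 24 h (adjusted p = 0.666, n = 59; r = -0.174, and 0.135 without the 2 farthest). It lay below the median of all genes (5.49) in 54 of the 59 lines, with a median of 3.58, so the ranks are mostly of background and decide nothing on efflux. NCI-ADR-RES, with the highest level (11.7), changed by 0.116 and its sister line OVCAR-8, at 3.80, by 0.505. HCT-15, CAKI-1 and UO-31, with ABCB1 at 9.74, 7.81 and 6.21, changed by 0.791, 1.47 and 1.24. The mean level of proteasome subunits in untreated cells gave rho = -0.163 at 6 h (adjusted p = 0.327, n = 58; r = -0.137, and -0.169 without the 2 farthest), which leaves a relation open, since a p-value over the threshold does not show its absence.

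For each count of changed genes, 100 splits were made by flipping the sign of whole lines, the real one included. The real split was the highest (1 of 100) at 100 nM and 2 h (5 genes, highest other 0). It was so at 10 and 100 nM and 6 h (42 and 115, highest other 0 and 0) and 24 h (632 and 986, highest other 10 and 0). The same held between doses at 2, 6 and 24 h (1, 2 and 2, highest other 0) and in untreated cells (1, highest other 0). Flipped signs pull mean changes toward 0, so few genes can reach a 2-fold mean in another split. On adjusted p alone the real split gave 659, 3551 and 4266 genes between doses at 2, 6 and 24 h, with 2, 174 and 0 the highest other. In untreated cells it gave 4432, with 1 the highest other. At 10 nM and 2 h all 100 splits gave 0 genes, so the 2-fold count does not exclude chance, while on adjusted p alone the real split gave 208 and the highest other 3. At 10 nM and 24 h another split gave 1209 genes on adjusted p alone, against 7909 for the real one. The number of gene lists at 100 nM and 6 h did not exclude chance (10, with 24 of 100 splits as high and 14 the highest other).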
